A study of Mus musculus with 6 samples.

How the data were processed

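Bulk RNA was measured in 6 castration-resistant prostate tumours from a genetically engineered mouse model. Per the labels' protocols, the mice were irradiated with 900 rad at 6 weeks of age and received bone marrow, were castrated at 8 weeks, and had their tumours resected 16 weeks after castration. The marrow came either from donors with intact floxed F10 alleles (the F10-intact group, 3 samples) or from donors that also carried LysM-Cre, which deletes F10 in myeloid cells (the F10-deleted group, 3 samples). F10 encodes coagulation factor X. Poly-A RNA was made into strand-specific libraries and read as single-end reads of 120 bases, per the labels' protocols.

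The authors deposited 1 table of raw read counts per Ensembl gene for the 6 samples. Per the submitters' processing notes, STAR 2.7.10a was used with the genome build GRCm38, and DESeq2 is named there with no version or role. The counting program, its strand setting and the annotation release are not given in the sources used here, so reads shared by overlapping genes or near-identical copies, such as Sbp and Sbpl or the Klk1 family, cannot be assigned with certainty. The table held 21718 genes, of which 40 had 0 counts in every sample. Gene symbols and coordinates were taken from GENCODE M21 on GRCm38, which matched 21605 identifiers and left 113 without a symbol. The total counts ranged from 9237308 to 11821588 per sample. Intervals on counts cover counting error only.

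The main test was the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust dispersion) on the deposited counts, with TMM factors and with genes kept by filterByExpr at a minimum count of 10, which left 15963 genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The F10 gene fell below the filter, so its fold change was taken from the same fit without a filter, and its groups were compared with an exact two-sided permutation test on log2(CPM + 0.5). Fold changes are F10-deleted over F10-intact, and CPM values use the TMM factors. The labels do not state that each sample was a separate animal, so p-values measure the spread between these samples.

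A total of 45 gene lists were fixed before the data were examined. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Lists needed at least 5 tested genes, and were tested again with camera's estimated correlation and with fry. Where stated, the edgeR p-values of members were also adjusted over their own list alone. Members of a list vary together, so those that pass in this way are not separate pieces of support. A fixed rule chose the genes named. It took F10 and Lyz2 in every sample. It took up to 12 genes per direction with the largest fold changes among genes past the threshold, with a mean CPM of at least 1 and no overlap between groups, leaving out unnamed gene models and immune receptor segments. Open places went to the smallest unadjusted p, as values and not as changes. It also took 2 to 4 members of each list with the smallest p. Members of lists that camera did not call are named only for 6 lists, chosen after their values were seen. Other genes named outside the rule are marked as such, and a few genes that the rule takes are not reported here.

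Both groups carry the replicate numbers 1, 3 and 4 in the labels. Samples with the same number deviated together from their group means, with correlations across genes of 0.35 for number 1, 0.135 for number 3 and 0.181 for number 4. All 3 exceeded 0.1, so the numbers were treated as pairing the samples, and a fit with the number as a block was run beside the main one. With 3 samples per group this is weak evidence of pairing, and the labels name no shared day, animal or litter. The main fit was therefore planned without a block, and its p-values ignore any pairing. No 2 samples of a group agreed within sampling noise: the chi-square per degree of freedom of same-group pairs ranged from 22.3 to 77.5.

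The alternatives were RLE and upper quartile scaling, scaling without the 50 most abundant genes, DESeq2 1.42.0, limma-voom with and without sample quality weights, no filter, a filter of at least 1 CPM in at least 3 samples, a non-robust fit, an adjusted p under 0.1, the replicate block, and leaving out each sample in turn. For lists, camera with an estimated correlation, fry, lists of 10 or more genes, and lists without shared genes were added. Covariates for the muscle list and the fat list, the block with DESeq2, and the block with an estimated correlation were chosen after seeing the data. The tests were run on simulated data drawn from these samples' means and library sizes for this comparison, over 15726 genes. At a true 2-fold change, edgeR recovered 20 of 50 genes and DESeq2 23 of 50, and at a 4-fold change both recovered 42 of 50. The simulated false calls were 4.24% of calls with edgeR and 10.2% with DESeq2. The simulated spread followed the trend of dispersion over expression, without gene-specific spread or pairing. These shares therefore need not hold for the real samples. In simulated lists of 20 independent genes, over 15963 genes, camera found 20 of 20 lists raised 1.5-fold and called 0 of 20 unchanged lists. Genes of real lists vary together, which that simulation does not include.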

Results

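RNA was profiled in whole prostate tumours of castrated mice whose blood system came from donor marrow. The 3 tumour samples with F10-intact marrow, numbered 1, 3 and 4, were set against 3 with marrow designed to lack F10 in myeloid cells, numbered likewise. The comparison asks how tumour gene expression differs when F10 is targeted for deletion in myeloid cells of the marrow. How complete the deletion was is not known from these data. The totals were 10724071, 11821588 and 10520465 counts in the F10-intact samples and 9237308, 11559980 and 11432480 counts in the F10-deleted samples, over 20143 to 20843 genes with a count. The first principal component held 49.0% of the variance and set F10-intact sample 4 apart from the other 5. Mitochondrial transcripts took 2.45%, 3.23% and 5.75% of the counts in the F10-intact samples and 3.14%, 3.23% and 4.58% in the F10-deleted samples.

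The targeted gene, F10 (ENSMUSG00000031444, chromosome 8, 13037308 to 13056676, plus strand, GRCm38), was close to the detection limit in both groups. It had 2, 6 and 17 counts in the F10-intact samples and 7, 4 and 9 counts in the F10-deleted samples. The mean level was 0.817 ± 0.834 CPM in the F10-intact group and 0.617 ± 0.244 CPM in the F10-deleted group (SD, n = 3 each), with an exact two-sided permutation p of 1 where the smallest possible is 0.1. The unfiltered edgeR log2 fold change was -0.38 (95% interval -1.91 to 1.16, adjusted p = 0.933), and it was 0.77 without F10-intact sample 4, -0.85 and -0.64 without F10-intact samples 1 and 3, and -0.07 and -0.60 without F10-deleted samples 3 and 4. A lower F10 level was not detectable at this depth in whole tissue. Gene totals do not show which exons the reads came from, and neither F10 nor Lyz2 checks the group labels. Lyz2, the myeloid lysozyme gene whose locus drives the Cre, had 187 ± 112 CPM in the F10-intact group and 246.5 ± 32.6 CPM in the F10-deleted group (SD, n = 3 each). Its edgeR log2 fold change was 0.40 ± 0.39 (SE), with an adjusted p of 0.772, and it ranged from 0.14 without F10-intact sample 1 (0.25 without sample 3) to 0.99 without F10-intact sample 4.

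In the F10-deleted tumours, 7 genes rose and 0 fell among 15963 genes tested with edgeR without the replicate block. With the block, 0 of the 7 passed. Of the 7, 4 encode proteins of striated muscle: Mybpc2, a fast myosin-binding protein, Myot and Myoz3, proteins of the Z-disc, and Txlnb, a muscle taxilin. The other 3 were Fabp4, a fatty acid carrier of adipocytes, endothelium and macrophages, Aqp4, a water channel, and Dram1, a lysosomal protein linked to autophagy. Each of the 7 was higher in all 3 F10-deleted samples than in any F10-intact sample. At an unadjusted p under 0.05 the test gave 981 genes with higher and 756 with lower values, a total of 1737, where another split of the samples gave 1284. DESeq2 called 351 higher and 130 lower, which included the 7. The groups did not overlap for 16.7% of genes, where chance gives 10% if the samples are exchangeable, a value that ignores the replicate pairing.

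Fabp4 (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576, minus strand) rose from 12.6 ± 2.63 to 119 ± 20.4 CPM (SD, n = 3 each), a log2 fold change of 3.24 ± 0.21 (SE, edgeR adjusted p = 0.00741). Aqp4 (ENSMUSG00000024411, chromosome 18, 15389496 to 15410982, minus strand) rose from 8.68 ± 2.17 to 41.3 ± 0.967 CPM, a log2 fold change of 2.25 ± 0.21 (edgeR adjusted p = 0.0386). Dram1 (ENSMUSG00000020057, chromosome 10, 88322804 to 88379080, minus strand) rose from 34.1 ± 2.47 to 79.9 ± 6.90 CPM, a log2 fold change of 1.23 ± 0.14 (edgeR adjusted p = 0.0476). Mybpc2 (chromosome 7, 44501699 to 44524656) rose from 1.24 ± 0.363 to 22.3 ± 8.34 CPM, Txlnb (chromosome 10, 17796226 to 17845665) from 0.519 ± 0.182 to 13.6 ± 5.83 CPM, and Myot (chromosome 18, 44334074 to 44355724) from 0.694 ± 0.162 to 13.8 ± 6.60 CPM. Their log2 fold changes were 4.15 ± 0.39, 4.66 ± 0.49 and 4.30 ± 0.46, with edgeR adjusted p of 0.0386 for Mybpc2 and 0.0476 for both others. Myoz3 (chromosome 18, 60573750 to 60591788) had 3 counts in the F10-intact group and 291 in the F10-deleted group, a ratio of 94.3 (95% counting interval 31.9 to 460, edgeR adjusted p = 0.0476). With the replicate number as a block, 0 of the 7 passed (edgeR adjusted p from 0.067 to 0.11) at blocked log2 fold changes of 3.24 for Fabp4, 2.27 for Aqp4, 1.23 for Dram1, 4.10 for Mybpc2, 4.56 for Txlnb, 4.22 for Myot and 6.40 for Myoz3, and the blocked fit called 2 other genes, named here after their values were seen. They were H19, an imprinted fetal transcript, at a blocked log2 fold change of 4.81 ± 0.20, and Klk1b26, a kallikrein, at -3.61 ± 0.14 (SE, edgeR adjusted p = 0.0203 for both). Without F10-intact sample 3 or F10-deleted sample 4 the unblocked test called 0 genes, without F10-deleted sample 1 it called 1, without F10-intact sample 4 it called 5, without F10-deleted sample 3 it called 18, and without F10-intact sample 1 it called 72.

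**Figure D1:**
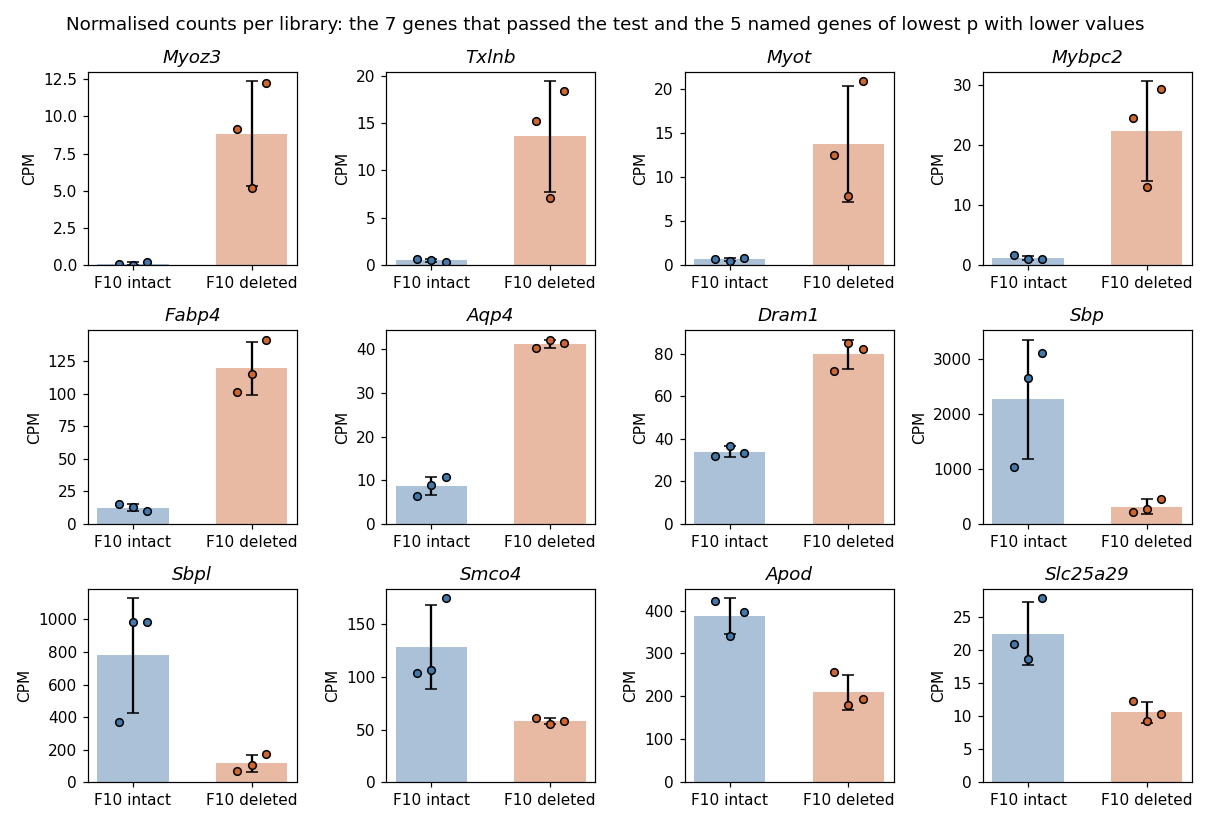
Normalised counts (CPM, linear axes from 0) in the F10-intact and F10-deleted groups for the 7 genes that passed the edgeR test and 5 named genes with lower values; points are the 3 samples of each group, bars the mean and error bars the SD. Fabp4 averaged 119 CPM in the F10-deleted samples and 12.6 CPM in the F10-intact samples, and Sbp 315 and 2262 CPM.

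Among genes that did not pass, the smallest p-values with higher values in the F10-deleted group belonged to Fn1, Nrap, S100g, Abra and Mylk2. Fn1, the matrix protein fibronectin, had a log2 fold change of 1.03 ± 0.12 and Nrap, a muscle anchoring protein, 4.36 ± 0.52 (SE, edgeR adjusted p = 0.0758 for both). S100g, a calcium-binding protein, was at 2.37 ± 0.30 and Abra, an actin-binding activator of muscle, at 4.70 ± 0.59 (edgeR adjusted p = 0.079 for both). Mylk2, the skeletal myosin light chain kinase, had 3 counts against 179, a ratio of 58.0 (95% counting interval 19.5 to 284, edgeR adjusted p = 0.0846). With lower values, the leading genes were Sbp and Sbpl, adjacent genes of prostate spermine-binding proteins on chromosome 17. Sbp stood at 2262 ± 1085 CPM in the F10-intact group and 315 ± 129 CPM in the F10-deleted group, a log2 fold change of -2.84 ± 0.48 (SE, edgeR adjusted p = 0.0974). Sbpl was at -2.72 ± 0.47 (adjusted p = 0.105, edgeR). Klk1, a glandular kallikrein, was at -3.11 ± 0.63 and Asgr2, an asialoglycoprotein receptor subunit, at -2.26 ± 0.47 (edgeR adjusted p = 0.142 for both). The log2 fold changes of the others were -1.15 for Smco4, -0.88 for Apod, an apolipoprotein, -1.09 for Slc25a29, a mitochondrial carrier, -0.76 for Cenpv, -1.73 for Hist2h3c2 and -0.74 for Hist1h1c, both histone genes, -0.90 for Bax, a promoter of apoptosis, and -0.60 for Magt1, with edgeR adjusted p from 0.108 to 0.135.

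Of the 45 gene lists, camera with a preset correlation called 17 higher and 4 lower in the F10-deleted tumours. With an estimated correlation 0 of the 45 passed, the lowest adjusted p being 0.35, and with fry 0 passed, the lowest being 0.0556. Other groupings of the same 6 samples also gave many camera calls: of 9 other splits into 3 and 3, the highest gave 20 lists. Each called list is given with both values, and a list called higher or lower is so by the preset test. With the muscle level as a covariate, chosen after seeing the data, the mitosis, cholesterol, fatty acid and ribosomal calls held. Of the others, 2 were called in the opposite direction and 15 were lost. The muscle list's own call is among the 15 and was lost by construction, since its mean is the covariate. The group holds 86.6% of the variance of that covariate, so these changes do not tell muscle RNA from a group difference. Except for Fabp4, 0 members of any list passed the test over all genes.

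Skeletal muscle genes were the most displaced list. All 17 tested members were above 0, with a median log2 fold change of 4.61 (quartiles 4.03 and 5.25, camera adjusted p = 2.83e-22), and 16 of 17 did not overlap between the groups. The adjusted p was 0.35 with an estimated correlation of 0.814, and 16 members passed when adjusted over the list alone. Actn3, a fast-fibre actinin, went from 1.29 ± 0.765 to 18.8 ± 9.08 CPM and Tnni2, fast troponin I, from 8.70 ± 5.53 to 159 ± 83.1 CPM (SD, n = 3 each), with edgeR adjusted p of 0.0846 and 0.0868. The muscle list took 0.0460%, 0.0196% and 0.0112% of the counts in the F10-intact samples and 0.308%, 0.139% and 0.303% in the F10-deleted samples. The adipocyte list was also higher, with all 12 tested members above 0, a median of 2.76 (camera adjusted p = 1.1e-07) and an adjusted p of 0.35 with an estimated correlation. Its members other than Fabp4 included Pck1, an enzyme of glycerol and glucose synthesis, at 0.507 ± 0.330 and 14.1 ± 11.2 CPM (edgeR adjusted p = 0.194), and 5 passed when adjusted over the list alone. Relative to the F10-intact mean, the list averaged 3.16, 1.00 and 3.39 log2 units in F10-deleted samples 1, 3 and 4 and 1.07, 0.01 and -1.08 in the F10-intact samples, so the groups overlapped.

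Genes of cell division were higher in the F10-deleted tumours by the preset test. All 25 members of the mitosis list were above 0, with a median log2 fold change of 0.94 (camera adjusted p = 8.4e-16, and 0.35 as the adjusted p with an estimated correlation), and 23 passed when adjusted over the list alone. The DNA replication list had all 25 members above 0 and a median of 0.48 (camera adjusted p = 4.88e-09, and 0.35 as the adjusted p with an estimated correlation), with 0 passing when adjusted over the list alone. Kif11, a spindle motor, had a log2 fold change of 1.27 ± 0.31 and Cenpf, a kinetochore protein, 0.90 ± 0.23 (SE, edgeR adjusted p = 0.201 and 0.219). E2f8, a repressor of the E2F family, was at 1.46 ± 0.33 and Mcm3, a subunit of the replicative helicase, at 0.85 ± 0.22 (edgeR adjusted p = 0.165 and 0.219). The mitosis list averaged 0.52, 0.77 and 1.39 log2 units above the F10-intact mean in F10-deleted samples 1, 3 and 4.

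Fibroblast, TGF-beta and endothelial lists were higher as well by the preset test, while the smooth muscle and pericyte list was not called (median 0.08, camera adjusted p = 0.222). The fibroblast and matrix list had 21 of 25 members above 0 and a median of 0.55 (camera adjusted p = 1.43e-07, and 0.35 as the adjusted p with an estimated correlation), and 9 passed when adjusted over the list alone. Its leading members were Fn1 and Col1a2, a collagen I chain that stood at 72.8 ± 6.28 and 135 ± 8.39 CPM (SD, n = 3 each, edgeR adjusted p = 0.0846). The TGF-beta and EMT list had a median of 0.26 (camera adjusted p = 7e-05, and 0.35 as the adjusted p with an estimated correlation). Ltbp2, a matrix protein named after the latent TGF-beta binding family, was at 1.05 ± 0.16 and Ccn1, a matricellular protein, at 0.72 ± 0.13. The median of the list was 0.09 without F10-intact sample 4 and 0.51 without F10-intact sample 1. The endothelial list had a median of 0.62 (camera adjusted p = 4.89e-05, and 0.397 as the adjusted p with an estimated correlation), with Emcn at 0.69 ± 0.21 and Plvap at 0.92 ± 0.34, and a median of 0.40 without F10-intact sample 4. Relative to the F10-intact mean, the endothelial list averaged 0.815, 0.483 and 0.277 log2 units in F10-deleted samples 1, 3 and 4. It averaged 0.504 in F10-intact sample 1, so the groups overlapped, and 0 members passed when adjusted over the list alone. Among the protease-activated receptor and coagulation genes, 15 of 19 were above 0, with a median of 0.28 (camera adjusted p = 0.00683, and 0.35 as the adjusted p with an estimated correlation). Plaur, the urokinase receptor, was at 0.62 ± 0.22 (SE, edgeR adjusted p = 0.347). That list call was lost without F10-intact sample 4 and without genes shared by lists (median 0.21, adjusted p = 0.128).

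Among epithelial lists, basal, squamous, urothelial and neuroendocrine genes were higher. The basal list had 13 of 15 members above 0 and a median of 0.87 (camera adjusted p = 1.11e-05, and 0.369 as the adjusted p with an estimated correlation), with Col17a1, a hemidesmosome collagen, at 0.84 ± 0.19 and Krt6a, a keratin, at 1.48 ± 0.37. Its groups overlapped, with averages of 0.597 in F10-intact sample 1 and 0.558 in F10-deleted sample 4, relative to the F10-intact mean. The squamous list had a median of 1.31 (camera adjusted p = 0.000161, and 0.35 as the adjusted p with an estimated correlation), with Dsc3, a desmosomal cadherin, at 1.19 ± 0.24 and Krt16 at 1.90 ± 0.44. The neuroendocrine list had 10 of 12 members above 0 and a median of 0.73 (camera adjusted p = 1.11e-05, and 0.35 as the adjusted p with an estimated correlation). Calca, a gene of calcitonin and a related neuropeptide, was at a log2 fold change of 1.13 ± 0.37 (SE, edgeR adjusted p = 0.323). The neuroendocrine median was 0.40 without F10-intact sample 4 and 1.34 without F10-intact sample 3, whose list average of 0.75 lay above the 0.58 of F10-deleted sample 4. The urothelial list had a median of 1.89 (camera adjusted p = 0.00829, and 0.412 as the adjusted p with an estimated correlation), and its call was lost without F10-intact sample 4. Its median was 2.91 without F10-intact sample 1 and 0.20 without F10-deleted sample 3. It averaged 0.74, 3.09 and 0.85 log2 units relative to the F10-intact mean in F10-deleted samples 1, 3 and 4 and 0.91, -0.04 and -0.87 in the F10-intact samples, with Krt20 at a log2 fold change of 4.67 ± 1.41 and Upk1a at 2.17 ± 0.67 (SE, edgeR adjusted p = 0.308 and 0.316), or 2.25 and 1.03 without F10-deleted sample 3. The luminal list was not called, with a median of -0.19 (camera adjusted p = 0.223) that ranged from -0.21 to -0.00764 with 1 sample left out. In it, Pbsn, the androgen-driven secretory gene probasin, had a log2 fold change of -1.91 ± 0.49 (SE, edgeR adjusted p = 0.233).

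Metabolic and stress lists moved in both directions. The fatty acid list had 21 of 22 members above 0 and a median of 0.34 (camera adjusted p = 2.07e-05, and 0.35 as the adjusted p with an estimated correlation), with Acaca, the first enzyme of fatty acid synthesis, at 0.75 ± 0.16 and Scd1, a desaturase, at 0.93 ± 0.22. The cholesterol list had 18 of 19 above 0 and a median of 0.46 (camera adjusted p = 5.53e-05, and 0.35 as the adjusted p with an estimated correlation), with Hmgcs1 at 0.86 ± 0.24 and Cyp51 at 0.89 ± 0.24. Its median was 0.30 without F10-deleted sample 3 and 0.73 without F10-deleted sample 1. The unfolded protein list was lower, with 18 of 20 members below 0 and a median of -0.41 (camera adjusted p = 1.65e-07, and 0.35 as the adjusted p with an estimated correlation), and 8 passed when adjusted over the list alone. Creld2 was at -0.71 ± 0.16 and Pdia6, a disulfide isomerase, at -0.74 ± 0.17. The ribosomal list was lower, with a median of -0.24 (camera adjusted p = 0.00138, and 0.478 as the adjusted p with an estimated correlation), Rps14 at -0.51 ± 0.23 (-0.31 without F10-intact sample 1) and Rpl11 at -0.32 ± 0.15. Its groups overlapped, with averages of -0.169 in F10-intact sample 4 and -0.0617 in F10-deleted sample 1, relative to the F10-intact mean. The hypoxia and glycolysis list was higher, with a median of 0.15 (camera adjusted p = 0.0167, and 0.367 as the adjusted p with an estimated correlation), Car9 at 1.34 ± 0.28 and Egln3 at 0.68 ± 0.17. The ribosomal call was lost without F10-intact sample 1 (median -0.07) and the median was -0.14 without F10-deleted sample 3, and the hypoxia call without F10-intact sample 1 or F10-deleted sample 1.

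Among immune lists, neutrophil and plasma cell genes were lower, and macrophage and T cell genes were not called. The neutrophil list had 14 of 16 members below 0 and a median of -0.60 (camera adjusted p = 0.000462, and 0.399 as the adjusted p with an estimated correlation). Its median was -0.30 without F10-intact sample 4, and the list averaged -0.42, -0.01 and 0.42 in the F10-intact and -0.64, -0.50 and -0.39 in the F10-deleted samples, relative to the F10-intact mean. The list was called higher with the muscle covariate (median 0.94, adjusted p = 0.0214). Lcn2, which epithelium also makes, stood at 539 ± 133 and 289.8 ± 63.3 CPM, and Csf3r, the G-CSF receptor, at 57.4 ± 14.3 and 36.4 ± 9.68 CPM (SD, n = 3 each, edgeR adjusted p = 0.228 and 0.393). The B and plasma cell list had a median of -0.67 (camera adjusted p = 0.00937, and 0.35 as the adjusted p with an estimated correlation), with Ighg2b at -2.05 ± 0.55 and Derl3 at -1.40 ± 0.56 (-0.78 without F10-intact sample 1). Its call was lost without F10-intact sample 4 (median -0.33) or F10-deleted sample 4 (median -0.43), and the median was -0.41 without F10-intact sample 1 and -0.45 without F10-deleted sample 1. The call was also lost with sample quality weights (median -0.13) and with no filter (median -0.30). The interferon alpha list was higher, with 24 of 25 members above 0 and a median of 0.41 (camera adjusted p = 0.000718, and 0.649 as the adjusted p with an estimated correlation), with Mx1 at 0.89 ± 0.32 and Usp18 at 0.75 ± 0.27 (0.48 and 0.44 without F10-deleted sample 4). It was called lower with the muscle covariate (median -1.02, adjusted p = 7.07e-05). It averaged 0.38, -0.05 and 1.13 log2 units relative to the F10-intact mean in F10-deleted samples 1, 3 and 4, against 0.55, -0.18 and -0.36 in the F10-intact samples. Its call was lost without F10-deleted sample 4 (median 0.08), and the median was 0.90 without F10-intact sample 1 and 0.67 without F10-deleted sample 3. The immune suppression list had a median of 0.27 (camera adjusted p = 0.0232, and 0.357 as the adjusted p with an estimated correlation), with Arg1, arginase, at 0.60 ± 0.19 and Nos2 at 0.91 ± 0.34. Relative to the F10-intact mean, the list averaged 0.112 in F10-intact sample 3, above the 0.0509 of F10-deleted sample 3. Its call was lost without F10-intact sample 4, F10-deleted sample 1 (median 0.16) or F10-deleted sample 4, and the median was 0.42 without F10-deleted sample 3. It was also lost with sample quality weights (median 0.12) and without genes shared by lists (median 0.08). The macrophage list had a median of -0.16 (camera adjusted p = 0.159) that ranged from -0.21 to -0.0585 with 1 sample left out. Its members included Mertk, a receptor for dying cells, at -0.64 ± 0.15 and Arg1 as given above. The T cell list had a median of -0.03 (camera adjusted p = 0.669), with Il7r at -0.46 ± 0.32 (-0.23 without F10-deleted sample 3) and Pdcd1 at 0.46 ± 0.38, and the cytotoxic list 0.13 (camera adjusted p = 0.345), with Gzmb at 1.42 ± 0.39 and Gzma at 2.10 ± 0.63 (1.18 without F10-deleted sample 1).

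The androgen response list was not called and split evenly, with 13 members above 0 and 13 below (median 0.00261, camera adjusted p = 0.898). Acpp, prostatic acid phosphatase, was at 0.77 ± 0.18 and Aldh1a3 at 0.91 ± 0.23. The ERK and AP-1 list had a median of 0.12 (camera adjusted p = 0.0569), with Epha2 at 0.99 ± 0.22 and Jun at 0.40 ± 0.12 (SE, edgeR adjusted p = 0.155 and 0.28). The other lists not called had camera adjusted p from 0.0532 to 0.779. Their median log2 fold changes were 0.21 for interferon gamma and MHC, 0.16 for senescence, 0.19 for matrix proteases, -0.34 for dendritic cells, 0.09 for Wnt and stemness, -0.09 for oxidative phosphorylation, 0.20 for heat shock, 0.08 for smooth muscle, -0.03 for PI3K-AKT, 0.09 for Schwann cells, -0.54 for erythroid cells, -0.62 for accessory glands, -0.10 for complement, -0.11 for inflammatory cytokines, -0.16 for mitochondrially encoded genes, -0.16 for sex chromosome genes, -0.42 for mast cells and eosinophils and 0.08 for mucins. With 1 sample left out, the matrix protease median ranged from -0.0332 to 0.349 and the senescence median from 0.0723 to 0.303. The median, the mean and the camera direction were not all of 1 sign for the androgen (mean -0.13, camera down), mast cell (mean -0.19, camera up), complement (mean 0.12, camera down) and mucin lists (mean -0.09, camera up).

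**Figure D2:**
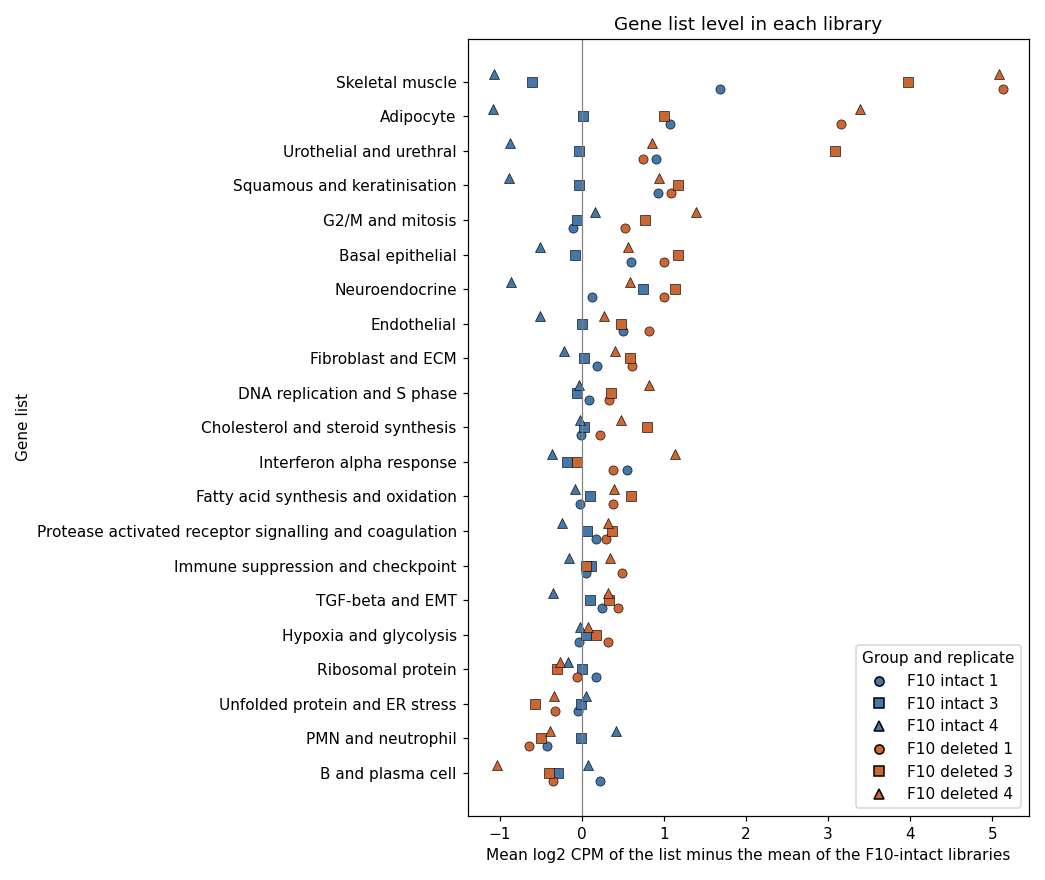
Mean log2 CPM of each of the 21 lists called with the preset correlation, per sample, relative to the mean of the F10-intact samples (0 on the horizontal axis); colours mark the groups and symbols the replicate numbers. The skeletal muscle list averaged 5.13, 3.97 and 5.08 in F10-deleted samples 1, 3 and 4 and 1.68, -0.61 and -1.07 in the F10-intact samples.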

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

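The covariates for muscle and fat and the block with DESeq2 or with an estimated correlation were chosen after seeing the data, and the other settings before. The count of 7 genes, all higher, was the same 7 genes with RLE, upper quartile and top-gene scaling, which moved the median of all genes by at most 0.0288, and it was 10 higher and 0 lower with no filter. DESeq2 called 481 genes (351 higher, 130 lower), limma-voom 2 (both higher), limma-voom with quality weights 175 (160 higher, 15 lower), the stricter filter 2, the non-robust fit 3, and an adjusted p under 0.1 gave 85 (84 higher, 1 lower). With the replicate block edgeR called 2 genes (1 higher, 1 lower), sharing 0 with the 7, and DESeq2 with the replicate block called 519 (355 higher, 164 lower). With the muscle covariate edgeR called 0 genes (0 higher, 0 lower), DESeq2 was not run with it, and 1519 genes had an unadjusted p under 0.05. Its log2 fold changes of the 4 striated muscle genes were 2.16 ± 0.86 for Mybpc2, 2.35 ± 1.23 for Txlnb, 2.99 ± 1.36 for Myot and 4.30 ± 2.02 for Myoz3. Leaving out 1 sample at a time gave 0 to 72 genes changed, 0 to 56 higher and 0 to 16 lower. With 0 called without F10-intact sample 3 or F10-deleted sample 4, edgeR gave 1565 and 1343 genes at an unadjusted p under 0.05. Other splits of all the samples gave up to 1284 such genes. Of the 7 genes, 7 lost their calls without either of these samples, 6 without F10-deleted sample 1, 5 without F10-intact sample 4 and 1 (Dram1) without F10-deleted sample 3. Among the other named genes, 10 were called without F10-intact sample 1 (Fn1, Nrap, Abra, Mylk2, Sbp, Sbpl, Col17a1, Col1a2, Actn3, H19) and 5 without F10-deleted sample 3 (Nrap, Abra, Mylk2, Pck1, H19). The 21 lists became 0 with an estimated correlation, 0 with fry, 0 in the replicate block with an estimated correlation and 10 with the muscle covariate, and 19 to 26 with 1 sample left out. Of those 10 lists, 4 were among the 21 in the same direction (mitosis, cholesterol, fatty acid and ribosomal), 2 in the opposite one (neutrophil and interferon alpha) and 4 were gained (accessory gland, smooth muscle, mitochondrially encoded, Wnt). The muscle level is largely confounded with the group, which holds 86.6% of its variance (a variance inflation of 7.45), so fold changes with it are imprecise. The replicate block with the preset correlation called the same 21 lists, and the block changed no call of another list. The fat covariate, of whose variance the group holds 57.2%, ended the calls of all 7 genes (Fabp4 at an adjusted p of 0.0678 and the other 6 from 0.131 to 0.18). The cause of these changes was not tested. A camera direction compares a list with the other genes, so it can turn without its median crossing 0. The pseudocount and low-value alternatives were not run because the table holds counts, and no list count was made with DESeq2 or the non-robust fit, which do not enter camera. Depth limits F10, whose counts were too few for the filter, so the stricter filter gave no value for it.

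The 21 list calls were all lost with an estimated correlation and with fry, which leave the medians as they were: -0.60 for PMN and neutrophil, -0.67 for B and plasma cell, 0.87 for Basal epithelial, 0.73 for Neuroendocrine, 0.55 for Fibroblast and ECM, 0.62 for Endothelial, 2.76 for Adipocyte, 4.61 for Skeletal muscle, 1.89 for Urothelial and urethral, 0.94 for G2/M and mitosis, 0.48 for DNA replication and S phase, 0.28 for Protease activated receptor signalling and coagulation, 0.41 for Interferon alpha response, 0.27 for Immune suppression and checkpoint, 0.26 for TGF-beta and EMT, 0.15 for Hypoxia and glycolysis, 0.46 for Cholesterol and steroid synthesis, 0.34 for Fatty acid synthesis and oxidation, -0.41 for Unfolded protein and ER stress, -0.24 for Ribosomal protein and 1.31 for Squamous and keratinisation. With limma-voom, list calls were gained at medians of 0.10 for ERK target and AP-1 and 0.19 for Interferon gamma and MHC. With sample quality weights, list calls were lost at medians of -0.13 for B and plasma cell and 0.12 for Immune suppression and checkpoint. With sample quality weights, list calls were gained at medians of -0.50 for Dendritic cell and 0.21 for ERK target and AP-1. With no filter, list calls were lost at medians of -0.30 for B and plasma cell. With the muscle covariate, list calls were lost at medians of -0.00299 for B and plasma cell, 1.09 for Neuroendocrine, 0.42 for Fibroblast and ECM, 0.20 for Skeletal muscle, 2.13 for Urothelial and urethral, 0.11 for DNA replication and S phase, -0.25 for Protease activated receptor signalling and coagulation, 0.30 for Hypoxia and glycolysis and -0.33 for Unfolded protein and ER stress. The skeletal muscle call was lost by construction, since the mean of that list is the covariate. Basal, endothelial, adipocyte, immune suppression, TGF-beta and squamous calls were lost with turned directions. With the muscle covariate, list calls were gained at medians of -5.82 for Seminal vesicle and other accessory gland. Smooth muscle, mitochondrially encoded and Wnt calls were gained with turned directions. Among lists of 10 or more genes, list calls were gained at medians of 0.21 for Interferon gamma and MHC. Without genes shared by lists, list calls were lost at medians of 0.21 for Protease activated receptor signalling and coagulation and 0.0828 for Immune suppression and checkpoint. At an adjusted p under 0.1, list calls were gained at medians of 0.12 for ERK target and AP-1, 0.21 for Interferon gamma and MHC and 0.16 for Senescence. With limma-voom, gene directions turned, at log2 fold changes of 0.05545 for F10. With sample quality weights, camera directions turned, at medians of -0.80 for Mast and eosinophil, -0.16 for Schwann and nerve, 0.29 for Erythroid, 0.00725 for Mitochondrially encoded and -0.33 for Mucin and gland secretion. With sample quality weights, gene directions turned, at log2 fold changes of 0.15 for F10. With no filter, camera directions turned, at medians of -0.65 for Mast and eosinophil and -0.0713 for Mucin and gland secretion. With the muscle covariate, camera directions turned, at medians of 0.94 for PMN and neutrophil, -3.92 for Mast and eosinophil, 0.41 for Luminal epithelial, -0.37 for Basal epithelial, -1.62 for Smooth muscle and pericyte, -0.56 for Endothelial, -1.07 for Schwann and nerve, -1.73 for Adipocyte, -0.17 for Androgen response, 0.026 for ERK target and AP-1, 0.0376 for PI3K-AKT, -1.02 for Interferon alpha response, -0.38 for Interferon gamma and MHC, 0.70 for Inflammatory cytokine and NF-kB, 0.0597 for Immune suppression and checkpoint, -0.063 for TGF-beta and EMT, 0.33 for Oxidative phosphorylation, 1.33 for Mitochondrially encoded, 0.20 for Squamous and keratinisation, -1.27 for Wnt and stemness and 0.71 for Sex chromosome. With the muscle covariate, gene directions turned, at log2 fold changes of 0.73 for Csf3r, 0.21 for Il7r, -0.25 for Gzmb, -0.40 for Krt6a, -0.84 for Pck1, -0.19 for Aldh1a3, -0.38 for Mx1 and -0.52 for Usp18. With the fat covariate, gene directions turned, at log2 fold changes of 0.01335 for Csf3r. Without genes shared by lists, camera directions turned, at medians of 0.00261 for Androgen response. Leaving out 1 sample at a time changed a call or a direction for these lists, and the direction of F10, whose values ranged as follows: F10 -0.85 to 0.77, Dendritic cell -0.36 to -0.12, T cell -0.20 to 0.23, Cytotoxic and NK 0.000257 to 0.46, B and plasma cell -0.72 to -0.33, Mast and eosinophil -1.17 to 0.19, Smooth muscle and pericyte -0.31 to 0.66, Schwann and nerve -0.26 to 0.29, Seminal vesicle and other accessory gland -1.35 to 0.96, Urothelial and urethral 0.20 to 2.91, Erythroid -0.83 to -0.19, Androgen response -0.13 to 0.0839, ERK target and AP-1 0.10 to 0.31, Protease activated receptor signalling and coagulation 0.24 to 0.38, Interferon alpha response 0.0789 to 0.90, Interferon gamma and MHC 0.0792 to 0.40, Inflammatory cytokine and NF-kB -0.25 to 0.0294, Immune suppression and checkpoint 0.16 to 0.42, Complement -0.13 to -0.00106, Hypoxia and glycolysis 0.11 to 0.22, Oxidative phosphorylation -0.15 to 0.0288, Ribosomal protein -0.27 to -0.0737, Mitochondrially encoded -0.37 to 0.27, Mucin and gland secretion -0.32 to 0.34, Wnt and stemness -0.16 to 0.54 and Sex chromosome -0.30 to 0.00978.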

Other observations

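Some genes differed widely between single samples, and the genes in this part and its tests on muscle, secretory and mitosis genes were chosen after their values were seen; the tests of other sample splits were chosen before. Myh8, the perinatal myosin heavy chain, had 29, 18 and 1 counts in the F10-intact samples and 1225, 444 and 1374 in the F10-deleted samples, while Myh7, the slow myosin, had at most 8 counts in any sample. Ucp1, a gene of brown fat, had 41, 3 and 78 counts in F10-deleted samples 1, 3 and 4 and at most 4 in the F10-intact samples. Krt20 and Upk2, genes of the urothelium, had 624 and 1788 counts in F10-deleted sample 3 and at most 72 and 188 in the others. Pate4, a gene of the male accessory glands, ranged from 70 to 40485 counts within the F10-intact group and from 3798 to 22898 within the F10-deleted group. The luminal keratins Krt8 and Krt18 and the adhesion gene Epcam had log2 fold changes of 0.02, -0.15 and 0.00.

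The 6 samples form 10 splits into 3 and 3, so no share of splits under 0.05 can be had. The real split gave 7 genes with edgeR, 481 with DESeq2 and 21 lists with camera, and 1 of 10 splits, the real one, gave as many in each case. The highest other split gave 1 gene, 120 genes and 20 lists. At an unadjusted p under 0.05, edgeR gave 1737 genes in the real split and 95 to 1284 in the others. Among the other splits that also part all 3 replicate pairs, the highest gave 0 genes with edgeR, 0 with DESeq2 and 20 lists.

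Skeletal muscle genes were higher in all 3 F10-deleted samples, as for Myh4, the fast myosin heavy chain, at 28.2, 1.63 and 1.04 CPM in the F10-intact and 643, 264 and 462 CPM in the F10-deleted samples; 9 of the 17 list genes were above 1 CPM in every F10-intact sample and 1 is in another list. RNA of skeletal muscle tissue in the resected samples is a candidate source, and 1 source would hold its genes in 1 ratio. Within groups the first component took 90.2% of the muscle list's variance, against a median of 63.6% and a 95th percentile of 86.2% in 1000 random lists of matched expression. Those random lists hold unrelated genes, which any genes that vary together could exceed, so this share cannot tell where the muscle RNA came from. A muscle-like programme in the tumours would hold such a ratio too, and the marrow genotype itself remains open and untested. For Fabp4, Aqp4 and Dram1, a fit with the muscle level as a covariate gave a median log2 fold change of 2.54, against 2.25 without it. The values went from 3.24 ± 0.21 to 2.54 ± 0.51 for Fabp4, from 2.25 ± 0.21 to 3.29 ± 0.46 for Aqp4 and from 1.23 ± 0.14 to 1.501 ± 0.357 for Dram1. Their calls ended (edgeR adjusted p from 0.491 to 0.517) as the errors grew for all 3, the Fabp4 value was smaller and the adjustment over all genes was harsher. Aqp4 had an unadjusted edgeR p of 0.000186 and an adjusted p of 0.491. With the fat level as a covariate the values were 2.97 ± 0.26, 2.58 ± 0.29 and 1.33 ± 0.21 (edgeR adjusted p from 0.0678 to 0.177). In F10-deleted samples 1, 3 and 4 the muscle list took 0.308%, 0.139% and 0.303% of counts. There Aqp4 was at 40.22, 42.12 and 41.45 CPM and Dram1 at 72.14, 85.35 and 82.21 CPM. As the muscle share fell from F10-intact sample 1 to 4, Aqp4 was at 6.37, 9 and 10.68 CPM. Dram1 was at 32.11, 36.86 and 33.28 CPM in those samples. These values per sample argue against muscle RNA as the main source for Aqp4 and Dram1. The fold changes with the covariate cannot decide it, because the group holds 86.6% of the variance of the muscle level. Fabp4 fell with the muscle share in F10-intact samples 1, 3 and 4, at 14.95, 13.03 and 9.75 CPM. It did not follow that share in F10-deleted samples 1, 3 and 4, at 101.3, 115 and 141.4 CPM. For Fabp4, a member of the adipocyte list, muscle RNA, fat RNA and the marrow group cannot be told apart.

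Sbp, Sbpl, Klk1 and Pbsn, secretory genes of the prostate, had lower values in all 3 F10-deleted samples, with a median log2 fold change of -2.78, and 0 of the 4 passed with edgeR, while DESeq2 called all 4 (adjusted p 2.18e-09, 1.8e-08, 2.24e-06 and 0.00307). With the muscle level as a covariate, Sbp went from -2.84 ± 0.48 to -0.50 ± 1.04, Sbpl from -2.72 ± 0.47 to -0.52 ± 1.09, Klk1 from -3.11 ± 0.63 to -0.37 ± 1.63 and Pbsn from -1.91 ± 0.49 to -0.85 ± 1.30 (edgeR adjusted p from 0.82 to 0.943), so the fold changes were not kept and the muscle level and the group cannot be told apart here. A lower share of epithelial RNA would lower luminal genes alike, and the other 23 luminal genes had a median of -0.17 (quartiles -0.56 and 0.19), which argues against it. A different mix of prostate lobes and glands cannot be told apart from a group difference, because the accessory gland list ranged over 3.25 log2 units within the F10-intact group and 3.99 within the F10-deleted group, and the labels used here record no lobe. The marrow genotype also stays open.

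Genes of mitosis were higher in the F10-deleted samples by the preset camera test. The difference did not rest on 1 sample of either group: the lowest list median was 0.84 with 1 F10-intact sample left out and 0.65 with 1 F10-deleted sample left out (without sample 4), and the camera call held each time. The call was lost with an estimated correlation (adjusted p = 0.35), so a shared swing of these genes between samples stays open beside the marrow genotype.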
